A study of Mus musculus with 2 samples.

How the data were processed

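H3K9me3 ChIP-seq was measured in 2 biological replicates of pooled mouse midbrain at embryonic day 11.5, from 109 and 88 embryos of strain B6NCrl. Per the labels, replicate 1 combined 2 technical replicates and replicate 2 had 1, the size range was 300 to 500 (unit not stated), and a control experiment exists, which was not analysed here. The deposited data used were 4 peak lists in narrowPeak format on assembly mm10, per the labels and the files' descriptions. One list was called on each replicate, one on both replicates together, and the list of replicated peaks was derived from the pooled list and the replicates' lists, per the files' descriptions. All 9035 replicated peaks had the same coordinates and enrichment as a peak of the pooled list. The aligner, the peak caller and their versions are not given in the sources used here.

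Each peak carries values that the authors computed. The enrichment is a linear ratio over control, deposited by the authors, without a stated normalization. The authors also deposited a −log10 p-value and a −log10 q-value per peak. The lowest −log10 p in any list was just above 2 (2.01), and a q of 1 was carried by 9.49% of the replicated peaks, 28.7% of replicate 1's and 0.732% of replicate 2's, so the lists include weak peaks. Of the replicated peaks 29.7% had a q of at most 0.05. The deposited browser score and the summit position were not used. The lists give no read counts, so depth per sample and the precision it sets are unknown, and a difference in list length can come from depth as well as from enrichment. Narrow peak calling can divide broad H3K9me3 domains into many short peaks, and how reads that align to several places were treated is not given in the sources used here.

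Peaks on chromosomes 1 to 19, X and Y were analysed (8820 of the 9035 replicated peaks). Those on unplaced or unlocalized scaffolds were left out. Coordinates are mm10, which has the same chromosome sequences as the GRCm38 reference used, and are given from 1. No peak of any list extended past its chromosome's end. Genes were from GENCODE M21, with 52194 genes of which 21938 are protein-coding. A peak was assigned to a gene or to another peak when they shared at least 1 bp.

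The main test moved all peaks of a chromosome by 1 random offset along the ungapped chromosome, with wrap-around, 1000 times (seed 20). This keeps peak lengths and clustering. Permutation p-values were two-sided, except for the overlap of replicates (one-sided), and the smallest possible were 0.002 and 0.001. They describe placement of one list along the genome and not variation among animals. Benjamini-Hochberg adjustment covered 4 annotation classes, 18 gene lists, the primer binding sites that had matches, or the length classes of coding exons. The 18 lists were zinc finger, odorant receptor, vomeronasal receptor, clustered protocadherin, keratin, defensin, cytochrome P450, replication-dependent histone, Hox, imprinted, germline, cleavage-stage, midbrain, housekeeping, liver, muscle, blood with vessel and mesenchyme, and heterochromatin regulator genes. Of 50 named midbrain genes 49 were found in the annotation, and 32 of 34 blood, vessel and mesenchyme genes. The 5 primer binding site sequences (18 bases) were searched on both strands and counted within 500 bp of a peak, beside their reversed sequences, which had no exact match and so gave no test. Domains were peaks merged at distances under 10 kb. Repeats were the lower-case bases of the reference. The uniqueness of a peak was the share of its 31-base words, sampled every 25 bases, that occur once in the assembly.

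Lists, tests and the rule for named genes were fixed before the data were examined. The rule took up to 3 genes per list by enrichment that also overlapped a peak of each replicate, the 10 protein-coding genes with the most peak sequence, the genes at the 5 strongest peaks, every imprinted gene with a peak within 5 kb, and midbrain or housekeeping genes with a peak if there were 5 or fewer. Genes named as contents of the 10 largest domains come from the description of domains. Alternatives were the pooled list, each replicate's own list alone, a −log10 q of at least 3, overlap of at least 50% of the peak, lists cut to equal length, promoters of 2 kb, overlap of at least 200 bp, promoter overlap, length-matched genes in 10 length bins, rotation including assembly gaps, the last 33.3% in place of the last 25% of the gene, primer sites with 1 mismatch or within 200 bp, and domains merged at 5 or 25 kb. Settings added after seeing the data were peaks in both replicates' own lists, peaks in which every sampled word was unique, and leaving out chromosome 7. Without a replicate, the other replicate's own list took the place of the replicated list.

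The code was tested on simulated data. Overlaps of replicated peaks with all 52194 genes were the same as those of bedtools 2.31.1. In 50 randomly placed peak sets, 2.44% of 900 list tests had a p under 0.05 and none passed after adjustment. When 10 of the 30 liver genes were given a peak, that list was called in 20 of 20 sets, and 1 other list was called. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.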

Results

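Trimethylation of lysine 9 on histone H3 (H3K9me3), a histone mark of heterochromatin and silenced repeats, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in the midbrain of mouse embryos of the inbred strain B6NCrl at embryonic day 11.5. All samples belonged to 1 group of 2 biological replicates. Replicate 1 was a pool of midbrains from 109 embryos and replicate 2 a pool from 88 embryos, each of both sexes. There was no second condition, so the comparisons are of one replicate with the other and of the peaks with the same peaks moved to random places. The deposited peak lists held 12213 peaks for replicate 1 and 30315 for replicate 2. A list called on both replicates together held 14559 peaks. The list of replicated peaks, a subset of that pooled list, held 9035 peaks covering 3.87 Mb with a median length of 336 bp, and is the main peak set here. The number of reads behind the lists is unknown, so no interval that needs read depth is given. Enrichment values are the authors' own ratio of each peak over control. The values given for replicates 1 and 2 come from their separate lists and show only that a peak was called there.

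The clearest accumulation of H3K9me3 lay over the clustered protocadherins on chromosome 18, genes for neuronal adhesion molecules of which each neuron uses a few. Of the 57 listed genes, 53 had a replicated peak in the gene body, against a mean of 6.67 when the peaks were rotated (adjusted p = 0.012, permutation test, two-sided). In replicate 1's own list 51 of the 57 genes had a peak, against 10.3 under rotation, and in replicate 2's own list 53 did, against 18.6, so the ratio was lower there (4.95 and 2.86, beside 7.95). The gamma cluster carried the domain with the most peak sequence, 80 peaks with 68.9 kb of peak sequence between 37655787 and 37771398, with 46.0 kb in replicate 1 and 79.1 kb in replicate 2. The alpha cluster (36929106 to 37026914) carried 44 peaks with 21.2 kb. Because gene bodies in these clusters are nested, the gene counts are not independent, and the 10 protein-coding genes with the most peak sequence were all annotated over this locus: the gene models Gm42416 (135 kb), Gm37013 (131 kb) and Gm37388 (130.0 kb), then Pcdhga1 (68.2 kb), Pcdhga2 (65.7 kb), Pcdhga3 (63.3 kb), Pcdhgb1 (59.7 kb), Pcdhga4 (57.7 kb), Pcdhgb2 (54.2 kb) and Pcdhga5 (51.3 kb). The strongest peak of the locus, at 37748078 to 37750458, had an enrichment of 6.70 and lay over a coding exon of Pcdhga10. The same peak was intronic to Pcdhga1 and Pcdhga2. Replicate 1 reached 6.09 and replicate 2 reached 8.61 within Pcdhga10.

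**Figure D1:**
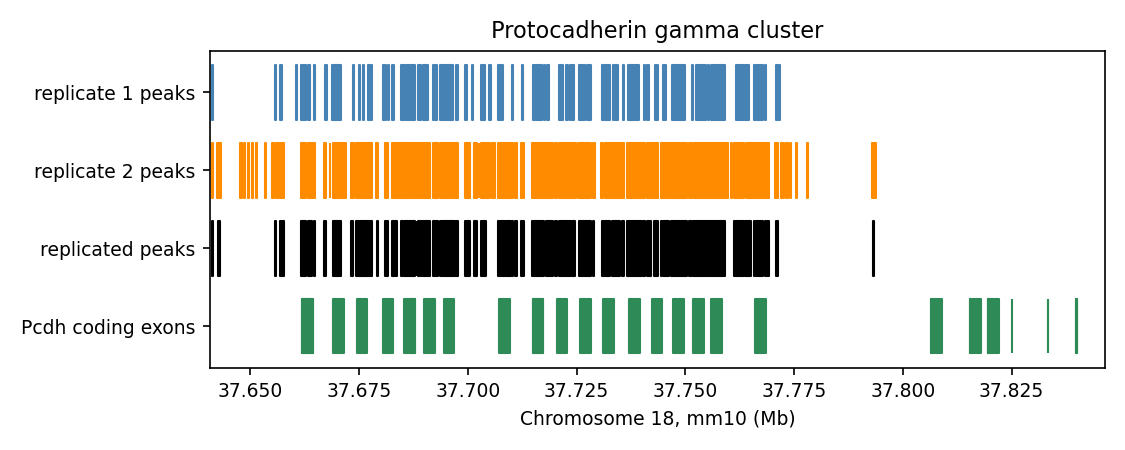
Map of the protocadherin gamma cluster on chromosome 18 (mm10, position in Mb on the x axis), with the peaks of replicate 1, of replicate 2 and of the replicated list above the coding exons of the Pcdh genes. Replicated peaks overlap the longest coding exon of every gene from Pcdhga1 to Pcdhga12 and of none of the 3 Pcdhgc genes at the right.

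Looking at each gene's longest coding exon, a measure chosen after the map had been seen, showed that the mark was not even across the cluster. In the 12 Pcdhga genes replicated peaks covered a median of 97.7% of that exon (78.2% with replicate 1's list, 99.1% with replicate 2's). In the 6 Pcdhgb genes the median was 69.9%, in the 12 Pcdha gene models 41.3% and in the 22 Pcdhb genes 29.7%. No peak of either replicate or of the replicated list touched the exon of Pcdhgc3 (37806548 to 37808977), Pcdhgc4 or Pcdhgc5, the C-type isoforms. Pcdhac2 also had 0 bp in all 3 lists, and Pcdhac1 had 293 bp of 2436 bp covered.

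Zinc finger genes, many of which encode KRAB repressors of transposable elements, had the largest number of marked members among the lists. A replicated peak lay in 122 of 420 genes, against 27.6 under rotation (ratio 4.42, adjusted p = 0.012, permutation test). The ratio was lower in the replicates' own lists, 3.07 in replicate 1's (124 genes against 40.4) and 2.44 in replicate 2's (179 against 73.5). Of these 122 genes, 105 also overlapped a peak in both replicates' own lists, and 28 lay on chromosome 7. At a −log10 q of at least 3, 41 of the 420 genes kept a peak, against 2.26 under rotation (adjusted p = 0.018, permutation test). The strongest was Zfp606 on the plus strand of chromosome 7 (12478293 to 12496235), with 13 peaks and a maximum enrichment of 8.24 (7.01 in replicate 1, 9.11 in replicate 2). Zfp68 on chromosome 5 (138603652 to 138619761, minus strand) reached 7.41 (5.86 and 8.79), and Zfp873 on chromosome 10 (82048123 to 82064745, plus strand) reached 7.11 (7.43 and 7.52). In all 3 the strongest peak covered coding exon and untranslated sequence toward the 3′ end, centred at 86.0%, 81.1% and 79.1% of the gene body.

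Across the family the peak sequence lay toward the 3′ end. Of the peak sequence inside zinc finger genes, 47.7% fell in the last 25% of the gene body, against a mean of 25.2% and a 95% range of 7.89% to 45.4% under rotation (p = 0.030, permutation test, two-sided) and 23.9% in other protein-coding genes. The share was 49.4% with replicate 1's list alone and 42.9% with replicate 2's. The first 10% of these genes held 1.27% of their peak sequence (95% range under rotation 1.16% to 22.6%). The last 10% held 20.2% (1.13% to 25.4%) and the 10% before it 20.4% (1.28% to 22.3%). Each of these shares lay inside its range, so taken singly they show no departure from rotation. The strongest peak overlapped a coding exon in 66 of the 122 genes and lay in an intron in 40. Peaks lay within 1 kb of the transcription start site in 3 of the 420 genes, against 4.58 under rotation. The 3′ excess was no longer past the threshold without chromosome 7 (46.2%, p = 0.112) or with peaks of unique sequence alone (46.7%, p = 0.052, permutation test). At a −log10 q of at least 3 the share was 60.7% (p = 0.335, permutation test). There the 95% range of rotations ran from 0% to 100%, so no share could have passed.

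**Figure D2:**
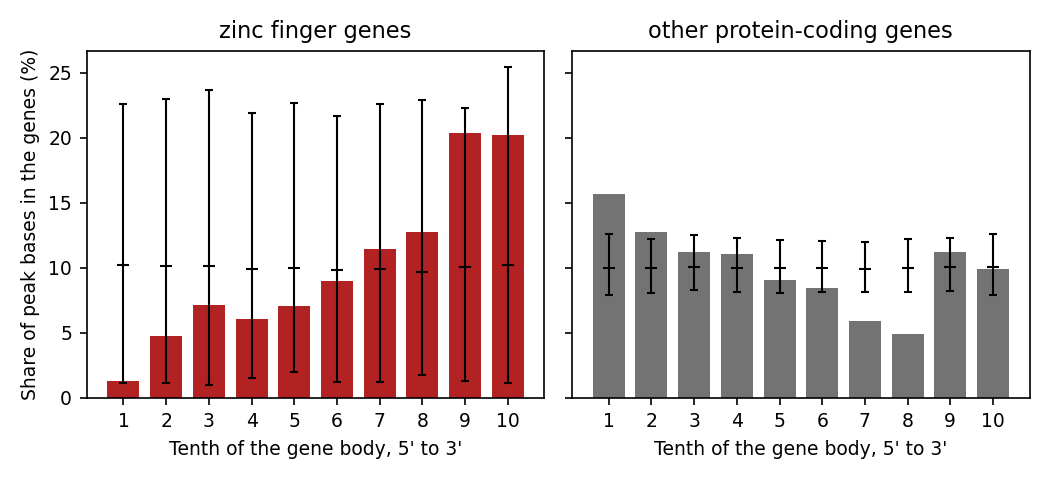
Share of the peak sequence within zinc finger genes (left) and other protein-coding genes (right) that lies in each successive 10% of the gene body, from 5′ to 3′, for the replicated list (bars, % on the y axis). Black marks are the mean and 95% range of 1000 rotations, and in zinc finger genes the share is 1.27% in the first 10% and 20.2% in the last, both inside that range.

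Imprinted genes, expressed from one parental allele, carried peaks in most listed members. Of 48 listed genes, 32 had a replicated peak in the gene body, against 4.84 under rotation (adjusted p = 0.012, permutation test), and 31 of the 32 also did in both replicates' own lists. The ratio of 6.61 was lower with replicate 1's list alone (4.55, 33 genes against 7.25) and replicate 2's (3.25, 39 against 12). Within 5 kb of the gene, 36 did, at 33 separate places, and 30 of those places held peaks in both replicates' own lists. The strongest peaks in gene bodies were in Mest on chromosome 6 (30738057 to 30738897, coding exon and UTR, enrichment 4.76, with 4.07 in replicate 1 and 5.71 in replicate 2), in Grb10 on chromosome 11 (12026558 to 12027569, UTR, 4.61, with 4.52 and 5.11) and at the promoter of Peg3 on chromosome 7 (6728885 to 6730561, 4.34, with 4.81 and 5.62), a peak that also lay within 5 kb of Usp29. Upstream of Igf2, the insulin-like growth factor gene of chromosome 7, 2 peaks between 142669245 and 142671429 reached 5.58 (6.09 and 5.89). The peak nearest H19, at 142580860 to 142581532, lay upstream of this non-coding RNA gene with an enrichment of 2.93 (3.85 and 3.35). Across the 36 genes the −log10 q of the strongest peak ranged from 0.198 (H19) to 6.49 (Igf2), so some of these peaks were weak. At a −log10 q of at least 3, 5 of the 48 genes kept a peak in the gene body, against 0.464 under rotation (adjusted p = 0.018, permutation test). Among these 5, Kcnq1 and the overlapping Kcnq1ot1 were counted for the same peak, at 143250699 to 143251695 on chromosome 7.

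At several loci the peak lay where an imprinted transcript sits inside a host gene. The strongest of 3 peaks on chromosome 17 (12741329 to 12743048) lay within 1 kb of the start of the non-coding Airn, in an intron of Igf2r, with an enrichment of 3.4. A peak on chromosome 7 reached 4.33 within Kcnq1ot1, in an intron of Kcnq1. Peaks marked the start of Zrsr1 within Commd1 (3.74), the neighbourhood of Peg13 within Trappc9 (3.32), of Nap1l5 within Herc3 (3.23) and of Nnat within Blcap (3.17). The Gnas and Nespas locus on chromosome 2 held 8 peaks between 174284688 and 174299931 with a maximum of 3.84. Meg3 (3.77) and Rian (3.94) on chromosome 12 both carried peaks, as did Plagl1 (4.15), Impact (4.25), Slc38a4 (4.05), Peg10 with Sgce (3.84), Cdkn1c (4.10), Snrpn with Snurf (3.03), Magel2 (3.33), Ube3a (3.64), Inpp5f (3.26), Zdbf2 (3.49) and, outside its body, Gpr1 (3.57). Ddc was the only one of the 36 without a peak in replicate 1's list (3.22, with 4.11 in replicate 2).

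Vomeronasal receptors, the pheromone receptors of the vomeronasal organ, had a peak in 53 of 327 genes against 16.8 under rotation (adjusted p = 0.018, permutation test). The ratio of 3.15 was lower with replicate 1's list alone (2.58, 60 genes against 23.3) and replicate 2's (2.11, 91 against 43.1). The strongest members were Vmn1r73 (4.35), Vmn1r82 (4.25) and Vmn1r70 (4.23), all on chromosome 7. Without chromosome 7 the call was lost but the ratio was close to the main one (24 of 173 against 7.69, ratio 3.12 beside 3.15, adjusted p = 0.084), and it was also lost with promoters alone (12 against 4.48, adjusted p = 0.468, permutation test). Germ cell and meiosis genes had a peak in 9 of 50 against 3.39 (adjusted p = 0.043, permutation test), all 9 also in both replicates' own lists. They included Meioc (3.65), a meiosis regulator, Dmrt1 (3.33), a gonadal transcription factor, and Sycp1 (3.33), a synaptonemal complex protein. In 6 of the 9 genes the strongest peak lay within 1 kb of the transcription start site, and with promoters alone the count was 6 against 0.302 (adjusted p = 0.012, permutation test). The germline call was lost with replicate 2's list alone (17 of 50 against 10, adjusted p = 0.065), with length-matched genes as background (ratio 2.18, adjusted p = 0.057) and with rotation over whole chromosomes (ratio 2.74, adjusted p = 0.0503, permutation test), beside a main ratio of 2.65. At a −log10 q of at least 3, no vomeronasal or germline gene had a peak, against 1.20 and 0.215 under rotation.

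Other lists did not pass the test. Odorant receptors had a peak in 50 of 1093 genes against 24.5 under rotation (adjusted p = 0.279, permutation test), led by Olfr139 (4.15), Olfr50 (4.05) and Olfr868 (3.74). Cytochrome P450 genes had 14 of 94 against 6.04 (adjusted p = 0.156, permutation test), led by Cyp3a57 (4.66), Cyp2b13 (3.95) and Cyp2c29 (3.95). Against random genes of matched length both lists passed (adjusted p = 0.0072 and 0.012, permutation test). Those genes were drawn singly, which does not keep the clustering of these families, so these p-values can be too small. The 95% range for odorant receptors was 23.0 to 42 genes there, against 7 to 58 under rotation. Without chromosome 7 the odorant receptors passed against rotation (44 of 857 against 13.4, adjusted p = 0.0090, permutation test). Regulators of H3K9 methylation had peaks in 4 of 27 genes against 2.27 (adjusted p = 0.795, permutation test). Among them Atf7ip (3.54, −log10 q 1.04) and Smchd1 (2.94, −log10 q 0.295) also overlapped peaks in both replicates' own lists. Setdb1 and Morc2a, named after their values were seen, did so only in replicate 2's. Single members had peaks in the defensin list (Defb33, 3.33), the cleavage-stage list (Pramef12, 3.12), the muscle list (Ttn, 3.23) and the list of blood, vessel and mesenchyme markers (Pdgfrb, 3.23), each with an adjusted p of 1. The −log10 q of the strongest peak in these single members ranged from 0.576 to 1.04. None of the 49 midbrain and neural genes had a replicated peak (2.52 under rotation, adjusted p = 0.279, permutation test), and neither did any of the 40 housekeeping genes (1.41, adjusted p = 0.906), 39 Hox genes (0.544), 68 replication-dependent histone genes (0.458), 141 keratin and skin-barrier genes (1.11) or 30 liver genes (1.11), the last 4 with an adjusted p of 1. With 0 inside the 95% range of the rotations for each of these lists, a depletion was not detectable with the replicated peaks. For the midbrain list 0 lay below the 95% range, 1 to 7, with the pooled list (adjusted p = 0.096) and with length-matched genes (adjusted p = 0.094, permutation test), neither past the threshold after adjustment, whereas replicate 1's list alone gave 3 of 49 against 3.84 (adjusted p = 1) and replicate 2's 4 against 7.47 (adjusted p = 0.324, permutation test), both inside the range.

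**Figure D3:**
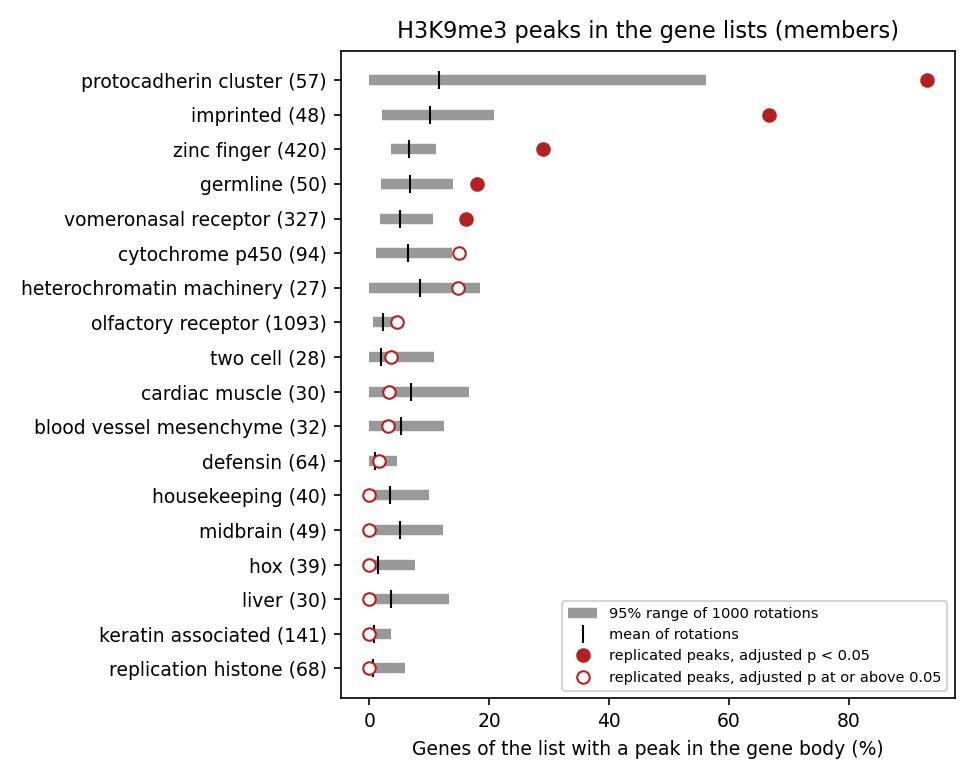
Share of each gene list with a replicated H3K9me3 peak in the gene body (circles, % on the x axis, with members in brackets), filled where the adjusted p was under 0.05. Grey bars and black ticks give the 95% range and mean of 1000 rotations, which protocadherins (93.0%), imprinted genes (66.7%), zinc finger genes (29.0%), germline genes (18%) and vomeronasal receptors (16.2%) exceed, as do cytochrome P450 genes (14.9%), which did not pass after adjustment.

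Of the 5 peaks of highest enrichment, 4 overlapped coding exons. The strongest, at 116024669 to 116025049 on chromosome 6, overlapped coding exon and UTR of Tmcc1, an endoplasmic reticulum membrane protein gene, with an enrichment of 9.84 (9.31 in replicate 1 and 10.4 in replicate 2). Klf14, a Krüppel-like transcription factor gene on the same chromosome, was covered by a peak of 2200 bp (30956496 to 30958695, enrichment 9.56, with 8.77 and 10.8). A peak on an unlocalized scaffold of chromosome 4 reached 8.52 (5.87 and 10.4). A peak of 3399 bp on chromosome 12 (80755783 to 80759181, enrichment 8.33, with 9.44 and 7.80) covered coding exon and UTR of Ccdc177 and the first part of the antisense gene Gm26796. The fifth was the Zfp606 peak (12493124 to 12494328).

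Peaks ran together in domains. Merging replicated peaks closer than 10 kb gave 4655 domains, of which 292 held at least 5 peaks and together 35.9% of the peaks. A protein-coding zinc finger gene lay in 37 of the 292. After the gamma protocadherins, the most peak sequence lay on chromosome 1 (88211405 to 88266810, 47.4 kb in 21 peaks), over the Ugt1a glucuronosyltransferase genes, Mroh2a and Hjurp, with another of the 10 largest domains close by over Trpm8, the cold-sensing channel gene (88280123 to 88310736, 24 kb). In this pair −log10 p was a median of 2.67 times that of peaks of the same enrichment elsewhere. Others covered Gm10775 and Zfp369 on chromosome 13 (26.7 kb), AU041133 and Zfp938 on chromosome 10 (25.1 kb), and Smok2a and Smok2b, sperm motility kinase genes on chromosome 17 (19.3 kb). Domains with no protein-coding gene lay on chromosome 4 (3049971 to 3091098, 23.8 kb, and 121998357 to 122059151, 21.9 kb) and at the start of the assembled sequence of chromosome 3 (3000055 to 3033359, 23.7 kb). The mean share of unique words was 72.1% in the Smok2a and Smok2b domain, and 86.5% and 88.4% in those on chromosome 4. It was 94.3% to 99.2% in the rest of the 10 largest domains and 96.1% over all replicated peaks. All 10 held peaks in both replicates' own lists. The number of domains was 7046 with the pooled list, 7488 with replicate 1's list, 14757 with replicate 2's and 330 at a −log10 q of at least 3.

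Chromosome 7 had the highest peak density. It held 4751 bp of replicated peaks per Mb, 3.4 times the density over all chromosomes, and the ratio was 2.89 in replicate 1 and 3.14 in replicate 2. Chromosomes 18 (1.76), 17 (1.75), 4 (1.57) and 13 (1.54) followed. Of the 103 zinc finger genes on chromosome 7, 28 had a peak, against 94 of 317 on the other chromosomes. Whether zinc finger genes account for its density was not tested. Chromosome X had a ratio of 0.220 (0.364 in replicate 1, 0.254 in replicate 2), and Y had 5 replicated peaks and a ratio of 0.030. The share of unique sequence on X was 0.832 of that on autosomes, and on Y 0.042. With a −log10 q of at least 3 the ratio of chromosome 7 was 2.12 and that of X 0.621.

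**Figure D4:**
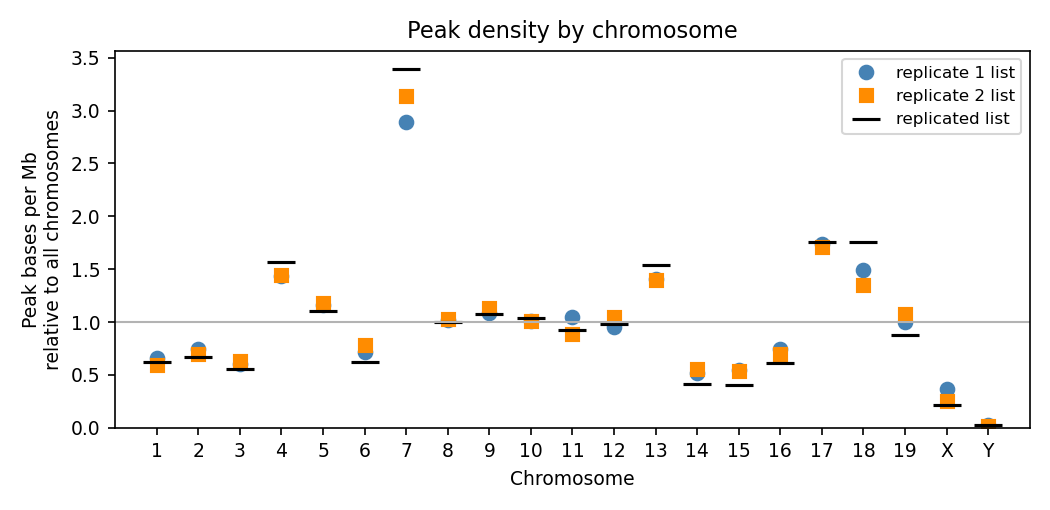
Peak bases per Mb of ungapped chromosome sequence, relative to the density over all chromosomes (y axis), for replicate 1 (circles), replicate 2 (squares) and the replicated list (short horizontal lines). Chromosome 7 stands at 2.89 to 3.4 and chromosome X at 0.220 to 0.364.

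Across the genome, promoters and exons held more of the mark than random placement gives. Promoters (1 kb on each side of a start site) held 9.27% of replicated peak sequence against 3.97% under rotation, and other exons 10.8% against 4.17%. Introns held 33.7% against 42.0% (adjusted p = 0.0027 for each of the 3 classes, permutation test). The intergenic share was 46.3% against 49.9% (adjusted p = 0.142, permutation test). With replicate 1's list promoters held 8.30% and exons 9.44%, and with replicate 2's list 7.04% and 7.42%. At a −log10 q of at least 3 exons held 23.7%, intergenic DNA 26.8% (adjusted p = 0.0027) and introns 36.3% (adjusted p = 0.513, permutation test). With promoters of 2 kb on each side the intergenic share was 43.3% (adjusted p = 0.044, permutation test). Coding exons were tested by length only with zinc finger, protocadherin, receptor and imprinted genes left out, and promoter sequence was not set apart there. Those under 500 bp held 1.03 times the peak sequence of rotation (adjusted p = 0.761, permutation test). Those of at least 1500 bp held 9.31 times. Whether short coding exons share the exon excess when all genes are kept was not tested. GC content and uniqueness were not matched in the rotation.

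The replicated peaks lay mostly in single-copy sequence. Repeats marked in the reference made up 21.9% of peak sequence against 33.9% under rotation, and GC content was 46.5% against 42.1% (p = 0.002 for each, the smallest value 1000 rotations can give in a two-sided permutation test). The repeat share was 21.4% in replicate 1 and 25.4% in replicate 2. Words of 31 bases sampled from the peaks occurred once in the assembly in 96.1% of cases, against 80.5% in the 8531 intervals that still had words to sample after all 8820 were moved once. Rotation also puts peaks in repeated sequence, where reads may not be placed uniquely. How such reads were treated is not known here. These shares therefore cannot tell a lack of the mark in repeats from a lack of placed reads.

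Retroviral primer binding sites, the 18-base sequences at which a tRNA primes reverse transcription and which mark proviruses, were close to peaks more often than rotation gives. Of 174 exact matches to the proline tRNA site TGGGGGCTCGTCCGGGAT, 8 lay within 500 bp of a replicated peak, against 0.576 under rotation. The counts were 19 of 1090 against 4.62 for the phenylalanine site, 4 of 67 against 0.355 for the lysine-1,2 site and 4 of 62 against 0.296 for the lysine-3 site (adjusted p = 0.0025 for each of these 4, permutation test). The glutamine site had 1 of 61 against 0.292 (adjusted p = 0.503, permutation test). The reversed control sequences had no exact match. Within 200 bp the proline site kept 8 matches, the phenylalanine site had 1 and the lysine-1,2 and lysine-3 sites 0, with 0.357, 2.94, 0.24 and 0.199 under rotation. At a −log10 q of at least 3 neither lysine site had a match near a peak, and the phenylalanine site had 2 (adjusted p = 0.35, permutation test). With replicate 1's list the phenylalanine (12 against 5.95, adjusted p = 0.087) and lysine-1,2 (2 against 0.439, adjusted p = 0.140) sites did not pass, and with peaks in both replicates' own lists the lysine-1,2 site did not (1 against 0.265, adjusted p = 0.480, permutation test). The proline site had 7 matches against 0.772 with replicate 1's list and 18 against 1.9 with replicate 2's (ratios 9.07 and 9.47, beside 13.9). In the same order, the lysine-3 site had 4 against 0.362 and 9 against 0.872.

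The replicates overlapped far more than chance but unequally. Of the 11952 peaks of replicate 1 on chromosomes 1 to 19, X and Y, 6633 (55.5%) overlapped a peak of replicate 2, against 0.944% under rotation. Of the 30049 peaks of replicate 2, 6264 (20.8%) overlapped one of replicate 1, against 0.377% (p = 0.001 for each, the smallest value of the one-sided permutation test). Shortening replicate 2's list to the length of replicate 1's by enrichment gave 35.4% and 31.3%, and requiring 50% of the peak gave 48.8% and 13%. Of the 9035 replicated peaks, 67.9% overlapped a peak in replicate 1's own list and 98.1% one in replicate 2's, and 66.1% overlapped both.

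Stronger peaks were shared more often. In replicate 1 the share found in the other replicate was 46.4%, 46.2%, 55.1% and 74.4% from the weakest to the strongest 25% by enrichment, and in replicate 2 it was 12.3%, 13.9%, 19.4% and 37.7%. Across the 6633 shared peaks the enrichment ranks of both replicates were weakly related (Spearman's rho 0.217, across peaks, which are not independent replicates, so no p-value is given). With both lists held to a −log10 q of at least 3, 72.9% of the peaks of replicate 1 (450 of 617) overlapped one of replicate 2, 8.45% of those of replicate 2 (395 of 4675) overlapped one of replicate 1, and rho was 0.534. In replicate 1 the weakest 25% then had the highest share, 91.6%, against 83.1% in the strongest.

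**Figure D5:**
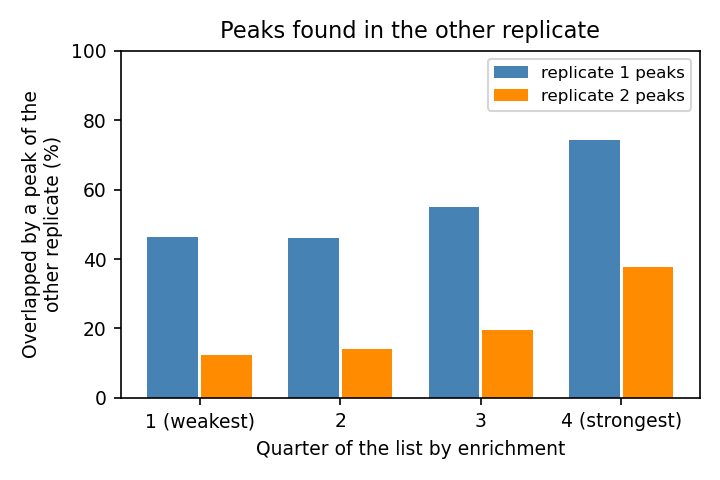
Share of the peaks of each replicate that a peak of the other replicate overlaps (y axis, %), for each successive 25% of its own list ranked by enrichment (x axis). The share is highest in the strongest 25%, 74.4% in replicate 1 and 37.7% in replicate 2.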

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

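Of the tests on zinc finger genes in this part, those with peaks of unique sequence and without chromosome 7 were chosen only after the result was seen, and the comparison with genes of matched length was planned but its bounds were set only after the result was seen.

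Peaks outside the chromosomes that the comparisons used were a signal in data left out of them. On unplaced or unlocalized scaffolds the replicated list held 215 peaks, the pooled list 243, replicate 1's list 261 and replicate 2's list 266. A single unplaced scaffold held 47, 47, 48 and 47 of them, respectively.

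The excess of zinc finger genes with a peak was weighed against 3 technical explanations, none of which the tables leave as its whole cause. If reads shared between paralogous genes made it, the excess would vanish for peaks of unique sequence, yet the ratio to rotation there was 4.66 (106 genes, adjusted p = 0.012, permutation test). If the peak-rich chromosome 7 made it, the rest of the genome would show none, yet the ratio without that chromosome was 4.78. Gene length is also excluded as the whole cause, since against genes of matched length the ratio was 4.59. Read length is unknown, and with a single tissue and stage no biological explanation was tested.

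The low density on chromosome X was weighed against repeated sequence and against a lack of clusters. On a grid of intervals the share of unique words on X was 0.832 of that on autosomes. That is too high to explain a density ratio of 0.220, which is relative to all chromosomes. At a −log10 q of at least 3 the density ratio of X was 0.621, nearer to 0.832, so the argument covers only the full replicated list. On Y the share of unique words was 0.042 of that on autosomes, near that chromosome's own density ratio of 0.030. Isolated peaks, with none other within 10 kb, were also scarce on X (0.149 of the autosomal number per Mb), which argues against missing clusters as the cause. The embryos were of both sexes, so X has fewer copies per cell than autosomes in the male part. That difference, and any difference in the chromatin of X, stay open and were not tested.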

How the results depend on the processing

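Unique peaks, peaks in both replicates' lists and leaving out chromosome 7 were settings chosen only after seeing the data. Of the alternative values for the main results, 97 kept their side of the threshold or stayed near the main value and 19 moved. Another 8 were no longer past the threshold and 3 newly passed it. In 5 a result that had passed in the main setting fell below a ratio of 1, none of these past the threshold. Results that passed in neither setting count among the 97 even where the direction changed, as for the glutamine site (ratio 0 at a −log10 q of at least 3, beside 3.42). Gene lists entered this tally only as the number of lists called, which hides exchanges. Without chromosome 7 the vomeronasal receptors no longer passed and the odorant receptors did. Taken list by list, 187 values kept their side of the threshold, 5 were no longer past it and 3 newly passed it. In 3 others a list that had passed in the main setting fell below a ratio of 1. Lists that passed in neither setting count among the 187 even where the ratio crossed 1. Odorant receptors, for example, had a ratio of 0 at a −log10 q of at least 3, beside a main ratio of 2.04. Depth is unknown, so what it limits cannot be separated from the choice of setting. At a −log10 q of at least 3, rho rose to 0.534. The shared share became 91.6% in the weakest and 83.1% in the strongest 25% of replicate 1, and 6.84% and 18.0% in replicate 2. Introns held 36.3% (no longer past the threshold) and intergenic DNA 26.8% (now past it). Lists called fell from 5 to 3, and vomeronasal and germline genes had a ratio of 0. The zinc finger 3′ share was 60.7% (not past the threshold, which no share could pass in this setting). The phenylalanine site had a ratio of 4.67 (not past), and both lysine sites had a ratio of 0. There were 330 domains, 26 with at least 5 peaks, and density ratios of 2.12 (chromosome 7) and 0.621 (X). This setting keeps 607 peaks, so expected numbers are small and a count of 0 shows no reversal.

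With replicate 1's list alone and replicate 2's list alone, in this order, the number of domains was 7488 and 14757, and those with at least 5 peaks were 302 and 792. Chromosome 7 had ratios of 2.89 and 3.14, X of 0.364 and 0.254, the phenylalanine site of 2.02 and 4.60 and the lysine-1,2 site of 4.56 and 14.5. The pooled list gave 7046 and 442 domains. Within 200 bp the phenylalanine ratio was 0.340 (1 match against 2.94) and both lysine ratios were 0, but with 0.24 and 0.199 matches under rotation 0 is the usual outcome and shows no reversal. With 1 mismatch the glutamine site passed (6.19). With promoters of 2 kb the intergenic share was 43.3% and past the threshold. With promoter overlap 3 lists were called, and the zinc finger ratio was 0.655, with an adjusted p of 1. The zinc finger 3′ share was 46.7% with unique peaks and 46.2% without chromosome 7, and the lysine-1,2 ratio was 3.77 with peaks in both replicates' lists, none of them past the threshold. Beyond the smaller sets and narrower windows themselves, the cause was not tested. No paired analysis was possible because there is 1 group.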

Other observations

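The exclusions of genes with clone names and of genes at the strongest peaks were chosen only after the result was seen; the bounds of the other tests were set before their values were seen.

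Coding exons at the strongest peaks led to the hypothesis that long coding exons carry H3K9me3 also outside the gene families. Of the genes at those peaks outside the families, only Ccdc177 has a coding exon of at least 1500 bp. With zinc finger, protocadherin, receptor and imprinted genes left out, coding exons of at least 1500 bp held 9.31 times the peak sequence that rotation gives (42699 bp in 44 of 1204 exons, adjusted p = 0.0030, permutation test). Coding exons from 500 bp to under 1500 bp held 2.92 times (adjusted p = 0.0030, permutation test), and those under 500 bp 1.03 times (adjusted p = 0.761). Without genes that carry only a clone or model name, some of which may be unlisted members of those families, the ratio for the longest class was 8.57 (36 of 1079 exons). The exon of Ccdc177 lay at one of the strongest peaks that led to the hypothesis and was counted in the test, and without the genes at those peaks the ratio was 8.92 (40898 bp in 43 of 1203 exons). Among the other exons were Map10 (68.1% of 2673 bp covered), Celsr2 (62.1% of 3310 bp), Celsr1 (61.4% of 3589 bp), Camta1 (57.3% of 1853 bp), Bcl11b (52.1% of 2012 bp), 3 exons of Zfhx3, and Nlrp5, Nlrp2, Nlrp9b and Nlrp4a on chromosome 7, chosen after their values were seen. Coverage across the 44 exons ranged from 3.49% to 98.0%, and the percentages named here are among the higher ones. Zfhx3 and Bcl11b encode zinc finger proteins outside the list, so the families were not left out completely. The result is consistent with the hypothesis. GC content was not matched, and the peaks are GC-rich, so GC remains open as a cause.

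Germline genes with a peak beyond the named 3 were Mael, Ddx4, Dazl, Sycp2, Piwil1 and Taf7l, listed here because the count is small. Their strongest peaks had enrichments of 2.97, 3.22, 2.58, 3.03, 3.03 and 2.82, and all but that of Piwil1 lay within 1 kb of the start site.

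The domains over Ugt1a, Mroh2a, Hjurp and Trpm8 on chromosome 1 (88211405 to 88310736, 43 peaks, 71.3 kb) had low enrichment, from 1.99 to 4.13, but long peaks of up to 10940 bp. A candidate explanation is that the samples hold more copies of this region than the assembly, which would raise the number of reads and so −log10 p at a given enrichment. The median ratio of −log10 p to that of peaks of the same enrichment (within 5%) elsewhere was 2.67 (quartiles 2.10 and 3.06), against quartiles of 0.977 and 1.02 for peaks outside the 10 largest domains and medians of 1 to 1.33 in the other 8 of these domains. Peak length was not matched. Of the other 8, the domains with the longest peaks, 6721 bp on chromosome 17 and 5779 bp on chromosome 4, had medians of 1.19 and 1.33, and the gamma protocadherin domain (up to 4029 bp) had 1. Within the pair, the Trpm8 domain, with peaks up to 3549 bp, had 2.43. The words of the pair were 99.1% and 99.2% unique in the assembly in the 2 domains, so repeated sequence in the assembly does not account for it. A part played by peak length, and high background from another source at this place, stay open, since no read counts or control values were used.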
